A study of Homo sapiens with 6 samples.

How the data were processed

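Total RNA from SW480 cells with a FOXC2 construct or the empty pBabe vector was labelled with Cy3 and hybridised to single-colour NimbleGen arrays, with 3 separate cultures per group, per the labels' protocols. Cells were grown with 10% serum, selected with puromycin at 0.5 μg/mL for 3 to 5 days and harvested at 90% confluence, per the labels' protocols. The deposited values are intensities on a linear scale. The authors processed them with RMA, per the submitters' processing notes, whose version, background settings and genome build are not given in the sources used here. As usually run, RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a feature, so a shift shared by all transcripts of a group would not be seen. The design text gives 45033 genes per chip, and 33497 features were analysed here, so 11536 were not. The values ran from 50.002 to 57044, so each analysed feature had an intensity of at least 50.002 on all 6 arrays. A feature below that level on any array is not analysed here, and genes that are silent in 1 group may be missing from the counts for that reason. Detection calls, slides and scan batches were not used here, so signal over background and batch were not assessed.

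Features were named from the platform's probe annotation alone. Of the features, 13730 had 1 gene symbol, 0 had several and 19767 had none here, and the named ones covered 12562 genes. A gene with several features was represented by the feature with the highest mean over the 6 arrays. Of 944 genes with several features, 205 had at least 2 that passed, and for 1 gene, BCCIP, passing features went in opposite directions. A further gene of the fixed set is not reported here. The order of genes along chromosomes came from a RefSeq gene table of assembly GRCh38.p14, used for neighbourhood only.

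Intensities were transformed to log2 with no offset, further normalization or filter, and the 3 FOXC2 arrays were compared with the 3 pBabe arrays feature by feature in limma 3.58.1 (lmFit and eBayes, R 4.3.3). P-values were adjusted with the Benjamini-Hochberg method over all 33497 features, and a feature passed at an adjusted p under 0.05. A log2 fold change is FOXC2 minus pBabe, and 1 on this scale is a 2-fold change. Before the data were examined, 29 gene lists were fixed. They covered forkhead, mesenchymal, epithelial, MET pathway, ERK output, WNT, NOTCH, vascular, TGF-beta, matrix protease, integrin, stem cell and intestinal genes. They also covered G1/S, G2/M, interferon, NF-kB, hypoxia and glycolysis, stress response, p53, sterol, respiratory chain, ribosomal, immediate early and histone genes, and markers of fibroblasts, endothelium, leukocytes, and neurons and liver. Each list was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. A list's members were also adjusted over the list alone.

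The genes named were set before the data were examined. They were a fixed set, the 10 largest rises and 10 largest falls among passing, non-overlapping genes whose higher group was brighter than the median feature, and up to 3 passing members per list. For a list with no passing member, the 1 with the lowest p was named. TNC, MUC1, KRT7, PIK3CB, BCCIP and, in the closing section, COL3A1, the HOXC and PSG genes, the genes that bound runs of neighbours, and CHGB, CPLX2, PDX1, SNAP25, RIMS2 and ISL1 were named after their values were seen. The alternatives were quantile normalization, median centring, the replicate number as a block, leaving out dim features, a trended robust prior, array weights, an offset of 16 before the log, means over a gene's features, and leaving out each array in turn. A feature was left out as dim where neither group's mean reached the median of all values, so 1 bright group kept it in.

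The steps were tested on simulated data for the comparison of FOXC2 with pBabe over 33497 features. Of 50 simulated features per size, 88% were called at a true log2 change of 2, 56% at 1, 4% at 0.5 and 0% at 0.3, and 5 of 33297 unchanged features were called. A small change can therefore be missed with 3 arrays per group. However, a far smaller share of features changed in the simulation than the 26.3% that passed in the data, which makes the adjustment stricter. The simulated shares may therefore understate how often changes of these sizes pass here. Of 99 random lists over 12562 genes, 0 were called by camera at the preset correlation. The simulated genes varied independently, so this does not test how often lists of correlated genes are called.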

Results

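Gene expression was measured on 6 single-colour Cy3 NimbleGen arrays in SW480, a human colorectal adenocarcinoma line, carrying either a retroviral FOXC2 construct or the empty pBabe vector. FOXC2 is a forkhead transcription factor known from vascular development and from epithelial-mesenchymal transition, the loss of epithelial traits in favour of mesenchymal ones. Each group held 3 arrays from 3 separate cultures, taken after puromycin selection at 0.5 μg/mL for 3 to 5 days. The values were normalized intensities of 33497 array features, of which 13730 carried the symbol of 1 of 12562 genes. Median intensities lay between 895 and 913 on the 6 arrays. Pearson correlations across features, which are not independent replicates, were 0.987 to 0.990 between arrays of a group and 0.958 to 0.964 between arrays of different groups. Precision is limited by the 3 arrays per group. The labels do not name separate transductions, so intervals and p-values measure the spread between cultures and may not cover that between selected populations.

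The comparison of FOXC2 with pBabe cells asked which transcripts differed between the cells with the FOXC2 construct and those with the empty vector, with the receptor MET among the genes of interest. FOXC2 itself was 3.42-fold higher in the FOXC2 cells (95% confidence interval 2.86 to 4.07), at a log2 intensity of 13.05 ± 0.0468 (SD, n = 3) against 11.27 ± 0.161 (SD, n = 3) in pBabe. MET, the receptor for hepatocyte growth factor, rose 2.18-fold (95% confidence interval 1.89 to 2.52). The epithelial and intestinal genes VIL1, EPCAM and CDH1 rose, although 6 of 29 epithelial genes fell and that set did not pass (camera adjusted p 0.0532). The matrix genes COL5A1, SPARC and FN1 fell while the matrix genes TNC (1.61) and MFAP5 (2.24) rose, and the interferon-stimulated genes OASL, MX1 and BST2 fell. Vimentin (VIM), the mesenchymal intermediate filament, did not pass the test, with a log2 fold change of 0.09 ± 0.0908 (SE).

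**Figure D1:**
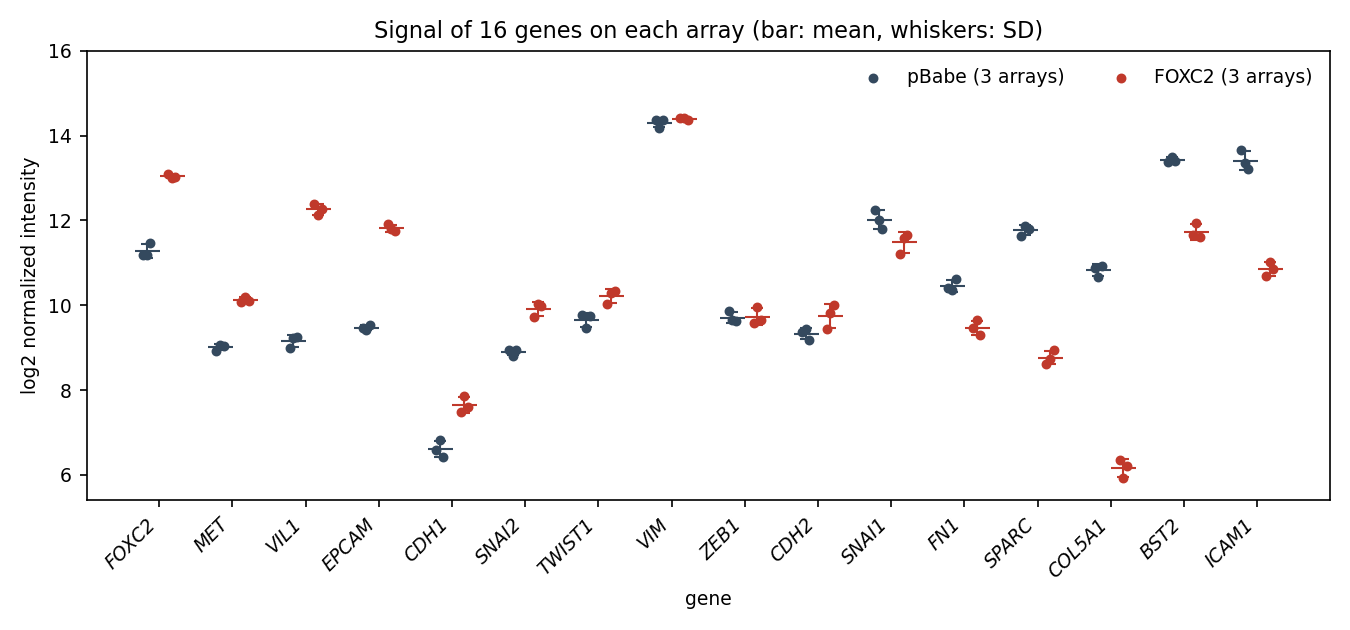
Log2 normalized intensity (vertical axis) of 16 genes (horizontal axis) on each of the 3 pBabe arrays and 3 FOXC2 arrays, with horizontal bars for group means and whiskers for 1 SD. FOXC2 lay between 13.01 and 13.10 in the FOXC2 cells and between 11.18 and 11.46 in pBabe, while the VIM values of the groups overlapped.

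The introduced gene checked the labels on every array. FOXC2 intensities were 8777, 8262 and 8344 in the FOXC2 cultures and 2319, 2323 and 2818 in the pBabe cultures. Its log2 fold change was 1.77 ± 0.107 (SE), with an adjusted p of 1.16e-04 by limma with Benjamini-Hochberg adjustment. MET intensities were 1082, 1180 and 1105 against 488, 532 and 527, a log2 fold change of 1.12 ± 0.0872 (SE) with a limma adjusted p of 3.04e-04. For both genes all 3 FOXC2 arrays lay above all 3 pBabe arrays.

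In all, 8819 of the 33497 features passed (limma, Benjamini-Hochberg), 26.3% of those tested, with 4450 higher and 4369 lower in FOXC2 cells. At least a 2-fold change was found for 942 of the higher and 1069 of the lower features, and for 442 and 553 with dim features left out. Taking 1 feature per gene, 3570 of the 12562 named genes passed, 1772 higher and 1798 lower. The groups did not overlap for 15233 features, or 45.5%, where chance gives 10%. The count of passing features was 5752 without FOXC2 replicate 3, and the count of higher ones 2732.

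**Figure D2:**
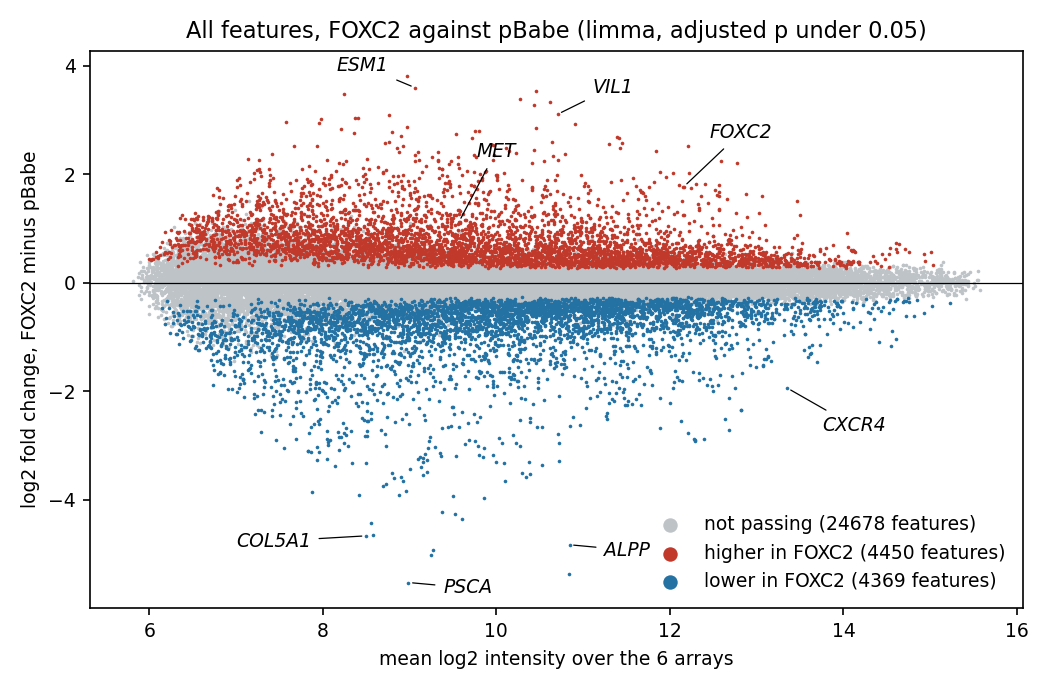
Log2 fold change of FOXC2 minus pBabe (vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis), 1 point per feature, coloured by whether it passed limma's test and in which direction. The 4450 higher and 4369 lower features spread over the whole range of intensity, and the largest falls, such as PSCA at -5.52, exceed the largest rises in size. PSCA lay near the lowest intensity of the table in FOXC2 cells, so the size of its fall is uncertain.

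The largest rises among named genes were of ESM1, a secreted proteoglycan of endothelial cells, at 12.1-fold, of DDC, which makes serotonin and dopamine, at 11.1-fold, and of LAD1, a basement membrane anchoring protein, at 10.1-fold. They were followed by GPX2, the gastrointestinal glutathione peroxidase (9.64-fold), VIL1, the actin-bundling villin of the brush border (8.62-fold), SLC6A4, the serotonin transporter (8.23-fold), and DKK4, a secreted WNT antagonist (7.22-fold). CPLX1, which regulates vesicle fusion, rose 6.99-fold, SPSB4 6.91-fold and CHGA, a granule protein of neuroendocrine cells, 6.70-fold. The limma adjusted p of these 10 genes was at most 3.91e-04, that of DKK4. In pBabe the mean intensities of DDC, SLC6A4 and ESM1 were 92.3, 117 and 155, near the lowest of 50.002 in the table, and without detection calls their folds and order are uncertain.

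The largest falls were of PSCA, prostate stem cell antigen, with a log2 fold change of -5.52 ± 0.410 (SE), and of the placental-type alkaline phosphatases ALPG, at -4.92, and ALPP, at -4.83. ALPG and ALPP are near-identical in sequence, and their probes may not tell them apart. The fibrillar collagen COL5A1 (-4.66), the homeobox gene EMX2 (-4.64) and the elastase inhibitor PI3 (-4.27) came next. BTG4 (-3.91), NTM (-3.74), the steroidogenic enzyme CYP11A1 (-3.66) and CRIP1 (-3.58) completed the 10. In FOXC2 cells the mean intensities of COL5A1, EMX2, PSCA and BTG4 were 72.2, 76.7, 86.2 and 88.9, and those of ALPG and NTM 115 and 121. These are near the lowest of 50.002 in the table, and without detection calls the sizes and order of these falls are uncertain. The limma adjusted p of these 10 genes was at most 5.06e-04, that of NTM.

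Of 26 measured mesenchymal and EMT-inducing genes, 12 fell, 3 rose and 11 did not pass (13 fell and 4 rose when adjusted over the list alone). The list was lower as a set (camera adjusted p = 0.0164, median log2 fold change -0.30; adjusted p = 0.335 with an estimated correlation). Among those that fell were COL5A1, the secreted matrix protein SPARC (-3.01 ± 0.118, SE), the growth arrest gene GAS1 (-2.76) and fibronectin, FN1 (-0.99 ± 0.123, SE; limma adjusted p 0.00198). The members that rose were TNC, SNAI2 and TWIST1, a matrix glycoprotein and a pair of transcription factors that repress epithelial genes. SNAI2 rose by 1.01 ± 0.114 (SE; limma adjusted p 0.00134) and TWIST1 by 0.56 ± 0.127 (SE; limma adjusted p 0.0191). TWIST1 no longer passed without FOXC2 replicate 2 (adjusted p 0.0624), FOXC2 replicate 3 (0.0663) or pBabe replicate 2 (0.0513). The log2 fold change was 0.02 (limma adjusted p 0.922) for ZEB1, 0.42 (0.102) for N-cadherin, CDH2, and -0.53 (0.0556) for SNAI1. CDH2 passed without FOXC2 replicate 1 (0.0299) and SNAI1 without pBabe replicate 3 (0.0499). Fibroblast markers moved with this list. Of 9 measured, 5 fell, among them COL1A1 (-2.22) and PDGFRB (-2.37), and 1 rose, MFAP5 (2.24); adjusted over the list alone, 5 fell and 2 rose (median -1.51, camera adjusted p 0.129). This set passed with a trended robust prior (0.0394) and with dim features left out (0.00120, 3 members, median -2.15). The dim filter keeps a gene by its brighter group, which favours changed genes, so the latter value adds no separate weight.

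Of 29 epithelial adhesion, keratin and splicing genes, 13 rose and 6 fell (14 and 6 when adjusted over the list alone). The adhesion molecule EPCAM rose by 2.35 ± 0.0870 (SE), the protease ST14 by 1.78, the tight junction protein MARVELD2 by 1.52 and E-cadherin, CDH1, by 1.03 ± 0.145 (SE; limma adjusted p 0.00318). CDH1 remained dim, at a log2 intensity of 7.65 ± 0.198 (SD, n = 3) in FOXC2 cells and 6.61 ± 0.194 (SD, n = 3) in pBabe. The mucin MUC1 (-0.88) and the keratin KRT7 (-0.76) fell. The set test did not pass (camera adjusted p = 0.0532), but did without FOXC2 replicate 1 (0.0471), pBabe replicate 1 (0.0449) or pBabe replicate 3 (0.0380), and on all arrays with a trended robust prior (0.0478) or array weights (0.0424).

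Differentiated intestine genes were higher as a set. Of 15 measured, 7 rose and 0 fell (8 and 0 when adjusted over the list alone; camera adjusted p = 0.0202; adjusted p = 0.279 with an estimated correlation). VIL1 rose by 3.11, CHGA by 2.74 and the intestinal homeobox factor CDX2 by 1.19. Much of the intestinal list was dim, with a median pBabe log2 intensity of 7.70. With dim features left out 4 members stayed, each kept by its brighter group (median 1.97, camera adjusted p 5.31e-04). A rise shared by dim genes was not tested apart. Of 14 markers used for colorectal cancer stem cells, 5 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.279 with an estimated correlation). The drug efflux pump ABCB1 rose by 2.21 and the pluripotency factors SOX2 and POU5F1 by 1.01 and 0.69. With dim features left out this list did not pass (camera adjusted p 0.136), although its median over the 8 members left was 0.22, as over all 14.

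Of 19 forkhead genes, 8 rose and 2 fell (8 and 3 when adjusted over the list alone; camera adjusted p = 0.0532). FOXA3, a factor of liver and gut, rose by 2.41, and FOXF1 fell by 1.52. The set passed without pBabe replicate 1 (0.0398) or pBabe replicate 3 (0.0373), and with a trended robust prior (0.0382) or array weights (0.0424). In the pathway of MET, 6 of 26 members rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.644). Besides MET, the kinase AKT2 rose by 0.99 ± 0.176 (SE; limma adjusted p 0.00808), and PIK3CB fell by 0.49. Of 21 output and feedback genes of the ERK pathway, 10 rose and 6 fell (12 and 6 when adjusted over the list alone; camera adjusted p = 0.408). PHLDA1 rose by 1.90 and EGR1 by 1.21, while the ETS factor ETV5 fell by 1.17.

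Of 23 interferon-stimulated genes, 15 fell and 0 rose, with the same counts when adjusted over the list alone. Among the 29 lists it had the lowest camera p at the preset correlation, though not with an estimated correlation or by fry (camera adjusted p = 2.59e-06, median -0.80; adjusted p = 0.279 with an estimated correlation). The antiviral genes OASL, MX1 and BST2 fell by 2.04, 2.01 and 1.69. Genes driven by NF-kB went both ways. Of 19, 4 rose and 6 fell (5 and 7 when adjusted over the list alone; camera adjusted p = 0.667), with the adhesion molecule ICAM1 at -2.54, the monocyte attractant CCL2 at -1.82 and the neutrophil attractant CXCL1 at 2.24.

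Mitosis and G2/M genes were lower. Of 28, 10 fell and 0 rose, with the same counts when adjusted over the list alone (camera adjusted p = 2.36e-04, median -0.27; adjusted p = 0.240 with an estimated correlation). NUSAP1 fell by 0.71 and BUB1 by 0.69. Of 26 replication and G1/S genes, 6 fell and 0 rose (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0520), including the primase subunit PRIM1 (-0.56) and thymidine kinase, TK1 (-0.48). The set passed without pBabe replicate 1 (0.0297) or pBabe replicate 2 (0.0383), and with a trended robust prior (0.0382), array weights (0.0424) or means over a gene's features (0.0415). Of 8 histone genes, 4 fell and 0 rose (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0562), and the linker histone H1-2 fell by 0.95. That set passed without FOXC2 replicate 1 (0.0439), pBabe replicate 1 (0.0449) or pBabe replicate 3 (0.0244), and with array weights (0.0424). Hypoxia-induced and glycolytic genes were also lower, with 10 of 31 falling and 2 rising (14 and 2 when adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.375 with an estimated correlation). The peptide hormone ADM fell by 1.68 and the glycolytic regulator PFKFB4 by 1.01, whereas EGLN3 rose by 1.16.

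**Figure D3:**
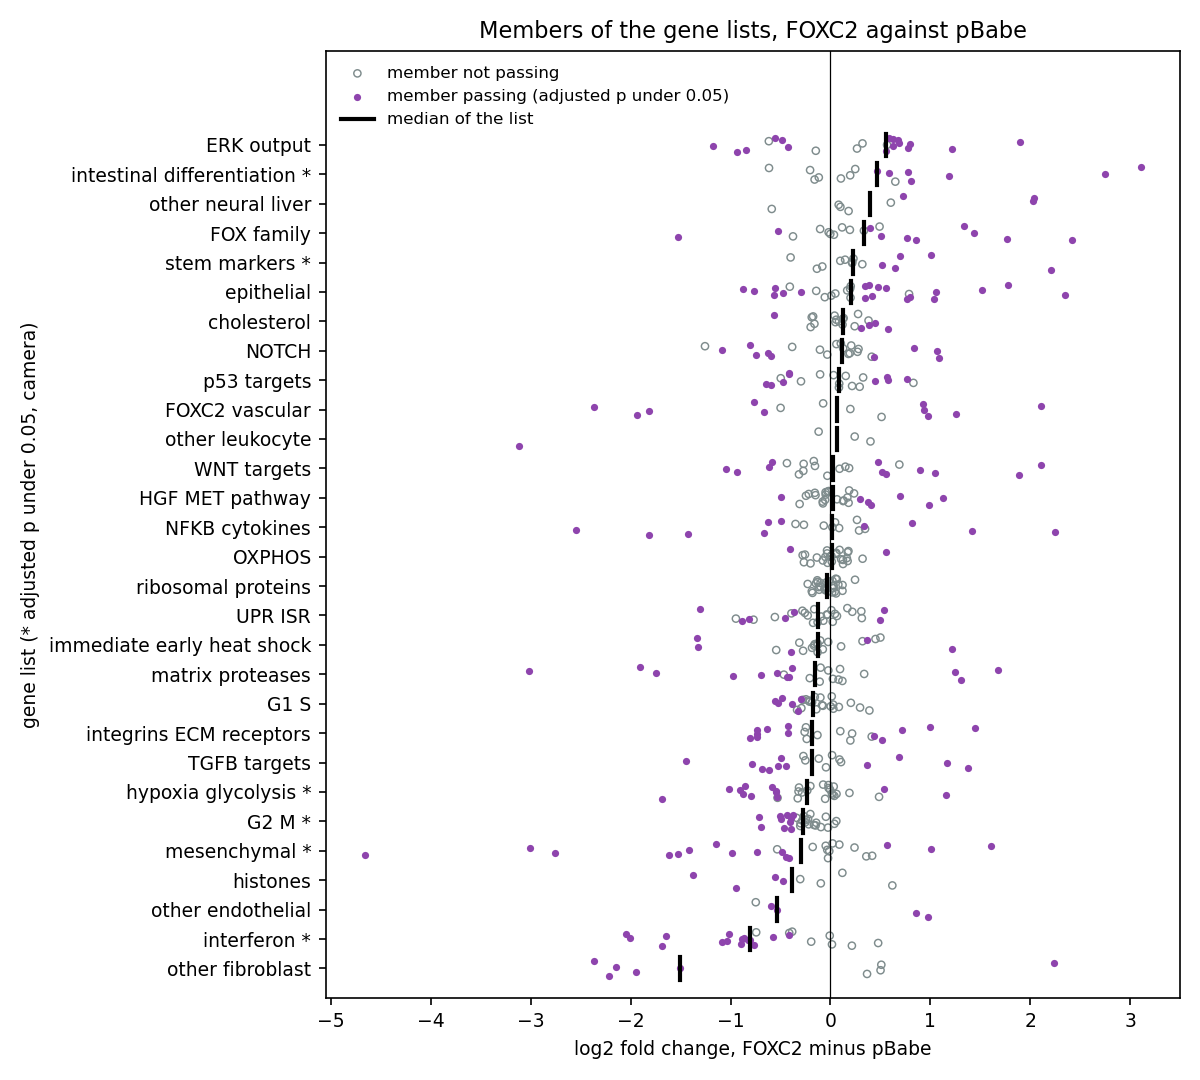
Log2 fold change of FOXC2 minus pBabe (horizontal axis) for the measured members of each of the 29 gene lists (vertical axis), with filled points for members that passed limma's test, open points for those that did not, a black bar for the list median and an asterisk where the camera adjusted p passed. The median was -1.51 for fibroblast markers and -0.80 for interferon-stimulated genes.

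Matrix and signalling lists were mixed. Of 22 matrix proteases and inhibitors, 9 fell and 3 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.129); the proteases MMP7 and MMP2 fell by 3.02 and 1.75 and the inhibitor TIMP3 by 1.91. Of 20 integrins and matrix receptors, 7 fell and 5 rose (8 and 5 when adjusted over the list alone; camera adjusted p = 0.667), with the proteoglycan SDC1 at 0.99. Among 18 TGF-beta targets, 7 fell and 4 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.358); SMAD6 fell by 1.45, and CCN2 rose by 1.38. Among 22 WNT targets, 7 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.701); PROX1 rose by 2.11 and ASCL2, a factor of intestinal stem cells, by 1.89. Of 22 NOTCH pathway genes, 4 rose and 5 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.980), and the ligands DLL1 (1.09) and JAG2 (1.07) rose while LFNG fell by 1.09. Of 14 genes tied to FOXC2 in vascular and lymphatic biology, 5 rose and 5 fell (5 and 6 when adjusted over the list alone; camera adjusted p = 0.667), with the chemokine receptor CXCR4 at -1.94.

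Of 29 ribosomal protein genes, 0 passed (0 when adjusted over the list alone, 1 at an unadjusted p under 0.05; camera adjusted p = 0.667), and the member with the lowest p, RPLP1, had a log2 fold change of -0.23 (limma adjusted p 0.0854). Of 26 respiratory chain genes, 1 rose and 1 fell (0 and 0 when adjusted over the list alone, 7 at an unadjusted p under 0.05; camera adjusted p = 0.980). Of 19 sterol genes, 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.408), and CYP51A1 rose by 0.58. Of 20 p53 targets, 4 rose and 5 fell (5 and 6 when adjusted over the list alone; camera adjusted p = 0.939), with PMAIP1 at 0.77 and DDB2 at -0.65. Of 29 genes of the unfolded protein and integrated stress responses, 2 rose and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.162), and VLDLR fell by 1.30. That list passed without pBabe replicate 3 (0.0221). Of 21 immediate early and heat shock genes, which respond to handling, 2 rose and 3 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.531), with NR4A1 at -1.33.

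Among markers of cell types that a pure SW480 culture should lack, 3 of 8 neuronal and liver genes rose and 0 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0562), including the synaptic vesicle proteins SYP (2.04) and SYN1 (2.03). That list passed without FOXC2 replicate 1 (0.0439) or pBabe replicate 1 (0.0449), and with a trended robust prior (0.0394). Of 5 endothelial markers, 2 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.980), and EGFL7 rose by 0.86. Of 4 leukocyte markers, 0 rose and 1, CD3D, fell by 3.12 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.813). With an estimated correlation 0 of the 29 sets passed, 4 had an unadjusted p under 0.05, and fry, which asks whether a set's genes move on balance one way, passed 18. For the G2/M, stem cell and intestinal lists the estimates were -0.00144, -0.0304 and -0.0512, below the preset 0.01. A higher correlation therefore does not account for their higher p. With an estimated correlation camera takes its degrees of freedom from the 6 arrays and not from the genes, which by itself raises p. For the interferon, mesenchymal and hypoxia lists the estimates were 0.0823, 0.0465 and 0.0713, above the preset. Both sources may add to the higher p of those lists, and their shares were not separated. The median and the set test differed in sign for the NOTCH, vascular, NF-kB, respiratory chain and leukocyte lists, and camera and fry did so for the NOTCH and endothelial lists.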

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

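The settings here were chosen before the data were examined. FOXC2 stayed between 1.73 and 1.87 and MET between 1.08 and 1.15 with each array left out, and both passed under every setting run. Of 803 named-gene results under the other settings, 783 kept their direction and side of the threshold, 13 no longer passed and 7 newly passed. With each array left out, 577 of 624 did so, 42 no longer passed, 2 newly passed and 3 changed sign. Whether same-numbered cultures were handled together is not given in the labels. The deviations of same-numbered arrays from their group means correlated at -0.102, -0.119 and -0.0615. Those of differently numbered arrays correlated at 0.0228 to 0.0890. No shared shift within a number was seen, but such correlations cannot settle how the cultures were handled. The replicate block gave 2917 higher and 3043 lower features (5960 in all). Means over a gene's features gave 3863 passing, 1927 higher and 1936 lower (427 and 477 at least 2-fold), because fewer units were tested. Without dim features 442 and 553 were at least 2-fold. Leaving out an array gave 5752 to 6768 passing features and 2732 to 3518 higher ones, the lowest of each without FOXC2 replicate 3. Of 29 lists, 11 passed with a trended robust prior, 10 with array weights, 0 with an estimated correlation and 18 by fry, and 6 to 11 with an array left out, 11 without pBabe replicate 1 and 10 without pBabe replicate 3. With an estimated correlation the adjusted p was 0.335 for mesenchymal genes, 0.279 for stem cell, intestinal and interferon genes, 0.240 for G2/M and 0.375 for hypoxia, and without dim features it was 0.136 for stem cell genes. In lists that never passed by camera the direction of the set test changed: NOTCH (0.990 with the block, 0.0701 by fry), integrins (0.881 without dim features), the respiratory chain (0.938 with quantile normalization, 0.962 with centring) and endothelial markers (0.114 by fry). With an array left out, the adjusted p ran from 0.826 to 0.985 for NOTCH, 0.789 to 0.985 for p53 targets, 0.818 to 0.973 for the respiratory chain and 0.687 to 0.999 for endothelial markers, all with changes of direction, and ZEB1 ran from -0.0891 to 0.1001. The median of 8 such lists changed sign under at least 1 setting, those of the MET pathway, NOTCH, vascular, integrin, NF-kB, WNT, respiratory chain and leukocyte genes, to values between -0.29 and 0.10. A single culture behind the lower interferon-stimulated genes was weighed too, in a test set aside after its result was seen, and that list had a median between -0.84 and -0.66 and an adjusted p of at most 1.07e-05 with each array left out. The causes of these changes were not tested, except where fewer units or arrays account for them. No detection calls were used here, so how far dim signals lie above background is unknown.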

Other observations

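The tests of gene families, secretory genes, array scaling, neighbouring genes, fibroblast markers and brighter mesenchymal genes were chosen after the data were seen. A scan of 222 families with at least 8 measured members passed 2 by camera at the preset correlation. With an estimated correlation camera's p was 0.0125 for HOXC and 0.0193 for PSG genes, and 0.989 for both when adjusted. That test has few degrees of freedom, so adjustment over 222 families is hard to pass. The 0.989 therefore does not decide against either shift. All 8 measured HOXC homeobox genes, which pattern the body axis, fell (camera adjusted p 1.32e-04, median log2 fold change -1.31), from -0.35 for HOXC10 to -1.74 for HOXC4. Of 10 pregnancy-specific glycoproteins (PSG), 9 rose and 0 fell (camera adjusted p 3.46e-04, median 0.98), PSG2 by 1.37 and PSG1 by 1.16. The PSG genes are near-identical in sequence, and whether probes of 1 gene report on another was not tested.

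Some genes of secretory granules and neuroendocrine cells, picked after their values were seen, rose, with CHGB at 2.22, CPLX2 at 2.68 and the endocrine factor PDX1 at 2.59 beside CHGA, CPLX1, DDC and SLC6A4. The vesicle gene SNAP25 did not pass, at 0.60 (limma adjusted p 0.0688). The hypothesis of a wider rise of such genes was tested on 21 members not looked at before. Of these, 7 rose and 2 fell, including the vesicle gene RIMS2 at 2.03 and the islet factor ISL1 at -1.30 (median 0.36). The camera p of 0.0884 did not meet the prediction of a p under 0.05, and the p was 0.221 with an estimated correlation. By fry, which does not compare the list with other genes, its members moved up on balance (p 0.00894), so a smaller rise is not excluded.

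Of 33497 features, 8819 passed. Under quantile normalization and median centring at least 8891 passed, but these moved log2 fold changes by at most 0.0971, less than their median SE of 0.121, so the count says nothing of an effect of the authors' normalization, which stays open. Of 1140 pairs of adjacent genes that both passed, 70.8% shared their direction (95% exact binomial interval 68.1 to 73.4, which treats pairs as independent), against 46.6 to 54.0% in 100 shuffled orders, a share below the 80% predicted of a copy number difference over chromosome segments and above the 60% that would argue against it, so that source stays open, although long runs shifted beyond shuffled orders held only 4.61% of placed genes. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many features, the real one. The highest of the others gave 0, but 10 splits are too few for a share under 0.05. Each of the others also mixes FOXC2 and pBabe arrays on both sides. This widens the spread within a side, so the 0 adds no support. The effect of FOXC2 and other differences between the selected populations stay open, since the labels name separate cultures and not separate transductions.

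Neighbouring genes shifted together in 8 runs holding 579 genes, with medians from -0.34 in the run from DIP2B to SPRYD4, which holds the HOXC genes, to 0.36 in that from CCDC146 to BHLHA15. In windows of 50 genes the largest distance of a median from that of all genes was 0.462, against at most 0.330 in 100 shuffled orders, and without the HOXC genes the median of their run was -0.31. FOXC2, MET, COL5A1, SPARC, EPCAM, VIL1, CDH1 and the PSG genes lay outside these runs. A shorter or weaker shift shared with their neighbours is not excluded, since only windows of 50 genes were scanned. The other named genes were not looked up, so some of their changes may belong to a run. All genes gave 6 runs of lower genes, and 4 runs of lower genes were chosen again on every other gene. Over these 4 the genes in between shifted toward the run by a median of 0.343. The shift was 0.398 from CSPG5 to RBM15B, 0.288 from TKT to C3orf38 and 0.465 from RARG to RAB5B. Chance clustering is argued against for those runs. In the run from ZDHHC4 to FKBP14 the shift was only 0.0894, with 14 of 24 genes in between toward the run. The run of lower genes from SORL1 to B3GAT1 was not among the 4, and 0 runs of higher genes were chosen this way. Chance stays open for the run from ZDHHC4 to FKBP14, that from SORL1 to B3GAT1 and the 2 runs of higher genes. Of the 115 genes in between, 76.5% shifted toward their run (95% exact binomial interval 67.7 to 83.9, which treats neighbours as independent). A copy number difference between the selected populations may underlie this, but regional regulation could give such a share as well and no DNA was measured, so they cannot be told apart.

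Of 26 mesenchymal genes, 12 fell, 3 rose and 11 did not pass in FOXC2 cells (camera adjusted p = 0.0164; adjusted p = 0.335 with an estimated correlation), although FOXC2 is known as an inducer of mesenchymal traits. Dim signals as the source are argued against for the 15 members with a mean above the median feature, of which 7 fell and 2 rose (median -0.41, camera p 0.0149, and 0.0995 with an estimated correlation), and the other 11 were not tested this way. Fewer fibroblasts in the FOXC2 cultures stay open, since 83.3% of the 6 fibroblast markers that passed were lower, although MFAP5 rose and COL3A1, abundant in fibroblasts, was dim in pBabe (percentile 5.42 of all features). An effect of FOXC2 and other differences between the selected populations may also contribute, and were not tested apart.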
